A study of Arabidopsis thaliana with 8 samples.

How the data were processed

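The series measured messenger RNA by sequencing in floral buds of mixed stages from Arabidopsis thaliana plants of the L er strain that carried the 35S:GR-RBE transgene. Per the labels' protocols, plants grew at 22 °C with 16 h of light and 8 h of dark. Buds received 10 µM dexamethasone in 0.1% ethanol and 0.015% Silwet (DEX), or the same solution without dexamethasone (mock), for 4 h. The 8 libraries comprised 4 per treatment, from 2 biological replicates with 2 technical replicates each. Poly-A RNA was purified, fragmented, made into adapter-ligated and PCR-amplified libraries and run on an Illumina Genome Analyzer, per the labels' protocols. The strand setting of the libraries was not given in the sources used here. TopHat 1.2.0, HTSeq 0.4.5p6 and the genome build TAIR10 were named in the submitters' processing notes, without their roles.

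The authors deposited 1 table of 28775 genes in the output format of LOX, a program that estimates relative expression levels from read counts by Markov chain sampling, per the file headers. For each gene and treatment the deposited level was a ratio to the lower treatment, which the authors set to 1. The table further held the authors' posterior probability of each direction, interval half-widths, an acceptance mark of the sampling and a log-likelihood score, per the file headers. All values were pooled over the libraries of a treatment, with 1 value per gene and treatment and no value per library. The planned quasi-likelihood test on counts summed per biological sample, its alternatives with other models and the planned tests of gene lists across samples therefore had no input. The fallback fixed for this case before the data were examined was used: the authors' estimates, their posterior and counts of list members by direction.

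Read depth was inferred from the deposited log-likelihood score, taken as the sum over both treatments of N ln(N/T) - N for N reads of a gene among T in total. No source used here states this formula, and every read number and counting error rests on it. For a gene with reads in 1 treatment, the score moved in steps that fitted whole reads to within 0.05 for 100% of the 908 such genes. The value of 1 read gave totals of about 102144599 reads assigned to genes in DEX and 119055461 in mock. With these totals, the score and the ratio of a gene gave its reads in each pool. Of the 8294 genes with up to 1000 reads and reads in both pools, 99.98% had a total within 0.1 of a whole number. The recovered reads of all genes summed to 102142647 and 119056377. Reads per pool are estimates from rounded deposited values, and the pools cannot be split into libraries.

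The log2 ratio of DEX over mock was taken from the authors' deposited table. Its standard error was computed from the recovered reads and covers counting error only. Across 8089 genes with more than 200 reads and a posterior between 0.02 and 0.98, the normal score of the authors' posterior rose with the ratio divided by this error with a slope of 1.00 and a Pearson r of 0.999. Genes are not independent replicates, and this relation describes how the posterior was formed. The authors' half-widths had a median of 1.02 times the counting error of the natural log ratio. Their headers name a level wider than 1 standard error, so this value is no check on the posterior. By the slope above, the posterior carried no visible term for the spread between biological replicates. Whether PCR copies of a molecule were removed before counting was not given. A gene was called higher or lower in DEX where the authors' posterior of the opposite direction was under 0.05 and both pools had reads. Counting error alone puts about 1 unchanged gene in 10 past this limit.

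Named genes followed a rule set before the data were examined. It took RBE and the MIR164 genes, and the 10 largest ratios in each direction among called genes with a mean of at least 50 reads per biological sample, or 200 reads over the 4 biological samples. It also took up to 4 members of each gene list with the smallest posterior of the opposite direction, with ties broken by the ratio over its counting error. The 19 lists, with 272 genes, were fixed before the data were examined. For each list, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from genes in the same of 20 bins of recovered reads. This placement describes the pooled libraries and is no test across replicates. It was added after the file was found to hold pooled values.

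Gene symbols, positions, exonic length, GC content and overlaps came from the RefSeq annotation of TAIR10.1, and 28009 of the listed loci matched it. Near-identical copies were sought with blastn 2.17.0 between exonic sequences, at 95% identity or more over at least 100 bases. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The recovery of reads, the calls and the list placement were run on simulated reads for 24599 genes. The simulation used the score formula above and a posterior from counting error alone, so neither assumption was tested. Its reads had no spread between replicates, its genes varied independently, and the changed genes had about 200 reads or more. Of genes changed 1.2-fold, 88% were called in the right direction, as were 100% of those changed 1.5-fold. Of unchanged genes, 9.87% were called. Of unchanged lists, 6% lay outside the central 95% of random lists. The alternatives tried were a posterior limit of 0.01, fold limits, filters on reads, scaling by the median of ratios and corrections for abundant genes, for GC content with length and for near-identical copies.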

Results

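RABBIT EARS (RBE) is a zinc-finger transcription factor of the SUPERMAN family needed for petal development. In 35S:GR-RBE plants a constitutive viral promoter drives RBE fused to the steroid-binding part of the glucocorticoid receptor, and dexamethasone lets the fusion enter the nucleus. The series compared buds treated with dexamethasone for 4 h (DEX) with mock-treated buds, to find genes downstream of RBE. Each treatment had 4 libraries, from 2 biological replicates with 2 technical replicates each, and the deposited values were pooled over them. The DEX pool held an estimated 102142647 reads assigned to genes and the mock pool 119056377. Of 28775 genes listed, 24945 had reads in both pools, 434 had reads only in DEX, 474 only in mock and 2922 in neither. Errors given below as ± are standard errors from read counting. With no values per library, no difference has a replicate check.

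RBE transcripts were abundant in both pools, with 21775 reads in DEX and 28895 in mock, a log2 ratio of -0.19 ± 0.01. The gene lies on chromosome 5 from 1828150 to 1829186 of TAIR10.1, on the minus strand, and reads of the transgene and of the native gene were counted together. The 3 MIR164 genes, whose microRNA restricts the CUP-SHAPED COTYLEDON boundary genes, were close to the limit of detection. MIR164A (chromosome 2, 19520752 to 19520864) had an estimated 5 reads in DEX and 3 in mock. MIR164B (chromosome 5, 287584 to 287736) had 15 and 26 reads, a log2 ratio of -0.56 ± 0.47. MIR164C (chromosome 5, 9852674 to 9852775) had 1 read, in mock. The posterior that DEX was higher was 0.801 for MIR164A and 0.103 for MIR164B in the authors' deposited table, so neither was called. The counting error was 1.04 for MIR164A, so at this depth small differences in these precursors were not detectable.

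The 4 TCP genes among the published RBE targets were called lower in DEX, TCP13 only slightly so. These transcription factors of the CINCINNATA class limit cell division in growing leaves and petals. TCP5 had the lowest ratio, at -1.15 ± 0.17, or 2.22-fold lower. TCP4 followed at -0.58 ± 0.03, with 3711 reads in DEX and 6454 in mock. TCP17 stood at -0.37 ± 0.16 and TCP13 at -0.10 ± 0.06. Of the 6 measured members of the published target list, 4 were called lower and 0 higher, and MIR164A and MIR164B were not called. The list median of -0.47 lay at percentile 0.17 of random lists. This list was chosen partly by the study's own group, on these or related samples, and is not independent evidence of direction. In the wider list of 11 CINCINNATA and CYCLOIDEA class TCP genes, which holds the same 4 TCP genes, 8 were called lower and 2 higher, or 9 and 1 with the median ratio of all genes set to 0. BRC1, a repressor of axillary bud growth, was at -1.31 ± 0.20 and TCP10 at -0.22 ± 0.03.

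Among called genes with 200 reads or more, TDR1 had the highest ratio of DEX over mock, 10.2-fold. TDR1 (AT3G23230), an ethylene response factor, had 180 reads in DEX and 21 in mock, a log2 ratio of 3.35 ± 0.34. SBT3.3 (AT1G32960), a subtilisin-like protease linked to immune priming, was at 2.46 ± 0.15. The gene AT3G12910 was at 2.59 ± 0.20, AT2G25735 at 2.46 ± 0.20 and the imprinted gene MPC (AT3G19350) at 2.26 ± 0.25. AT1G17147, which encodes a VQ motif protein, was at 2.18 ± 0.16, and AT3G29000, an EF-hand calcium-binding protein, at 2.00 ± 0.13. The Toll-interleukin receptor domain gene AT2G20142 was at 1.91 ± 0.12. The MATE efflux carriers DTX1 (AT2G04040) and AT5G52050 were at 1.85 ± 0.08 and 1.84 ± 0.16. DTX1 shares 551 aligned bases at 97.1% identity with AT2G14661, and DTX1 and SBT3.3 overlap genes on the other strand, so their reads are uncertain.

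The lowest ratio among these genes was that of AT3G61111, 6.12-fold lower in DEX, and XTH7 had the most reads of the 10 lowest. XTH7 (AT4G37800), a xyloglucan endotransglucosylase, had 907 reads in DEX and 3966 in mock, a log2 ratio of -1.91 ± 0.05. ATCSLA15 (AT4G13410), of the cellulose synthase-like family, was at -2.50 ± 0.21. OFP12 (AT1G05420), of the OVATE family of growth repressors, was at -2.09 ± 0.15. FRO6 (AT5G49730), a ferric reductase, was at -1.88 ± 0.06. The heat shock 70 gene ERD2 (AT1G56410) was at -2.30 ± 0.11 and the O-acetylserine lyase gene OASA2 (AT3G22460) at -2.04 ± 0.15. AT3G61111, annotated as a ribosomal protein, was at -2.61 ± 0.19. MYB47 (AT1G18710) was at -1.95 ± 0.25, AT3G09450 at -1.96 ± 0.25 and AT3G03670 at -1.96 ± 0.24. FRO6 shares near-identical sequence with its neighbour AT5G49740, and its reads are uncertain to that extent.

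**Figure D1:**
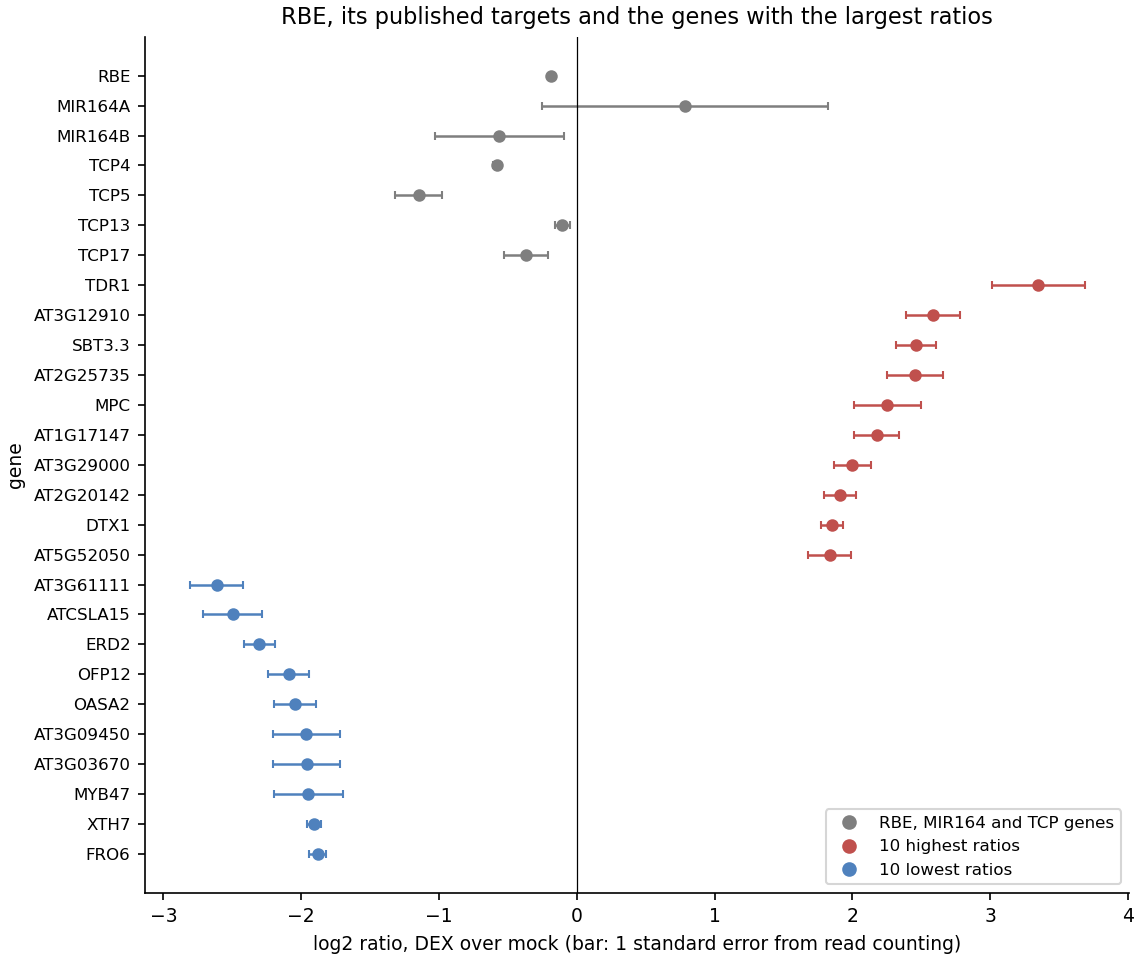
Log2 ratio of DEX over mock for RBE, MIR164A, MIR164B and 4 TCP genes (grey), the 10 highest ratios (red) and the 10 lowest (blue) among called genes with 200 reads or more. Points are the authors' estimates for pooled libraries and bars 1 counting standard error. The ratios run from -2.61 for AT3G61111 to 3.35 for TDR1.

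Most genes differed little between the pools. Of the 19983 genes with at least 200 reads, 95.1% had a ratio within 1.5-fold. The calls comprised 9081 genes higher and 5183 lower in DEX, at a depth where the median gene had 3154 reads. Together these were 57.2% of genes with reads in both pools. At 1.5-fold or more, 1109 called genes were higher and 727 lower, and with 200 reads or more these were 498 and 485. At 2-fold or more with 200 reads or more, 111 were higher and 106 lower. The excess of higher calls depended on the scaling: with the median ratio set to 0, 6339 genes were called higher and 7352 lower. That setting lowers every log2 ratio, and so every list median, by 0.05. Among genes with 3000 to 10000 reads the log2 ratios had an SD of 0.226, against a median counting error of 0.0386. Without values per library, the share of that spread due to variation between replicates was not measured.

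**Figure D2:**
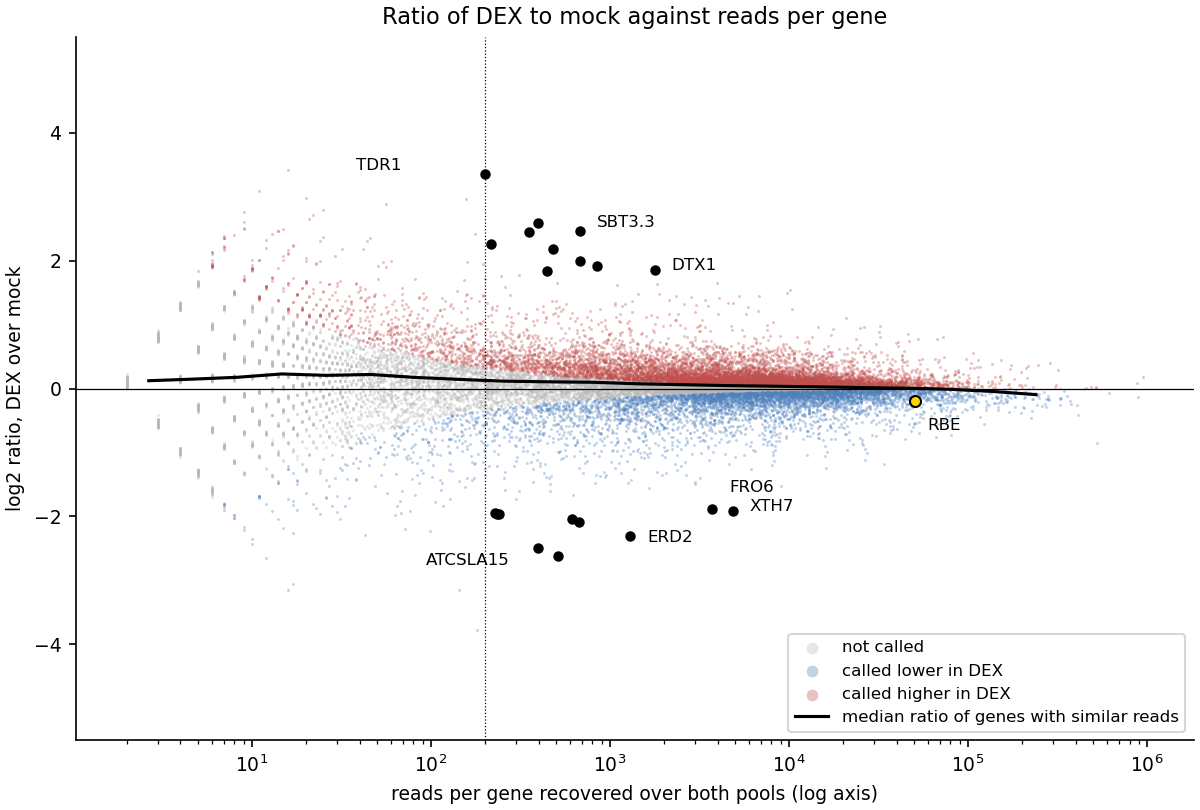
Log2 ratio of DEX over mock (vertical axis) against the reads recovered per gene over both pools (horizontal log axis) for genes with reads in both. Red and blue points are genes called higher and lower in DEX, black points the 20 named genes, the yellow point RBE and the black line the median of genes with like reads. The dotted line marks 200 reads. The median was 0.22 for genes with 10 to 50 reads and 0.04 for genes with 3000 to 10000.

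Regulators of organ growth were mostly lower in DEX. Of 22 measured genes, 15 were called lower and 5 higher, or 15 and 3 with the median ratio set to 0, and the median of -0.24 lay at percentile 0 of random lists. GRF7 and GRF3, of the growth-regulating factors that promote cell proliferation, were at -1.56 ± 0.08 and -0.87 ± 0.03. All 9 GRF genes were called lower, with ratios from -1.56 to -0.17, and this family was singled out after its values were seen. It makes up 9 of the 15 lower calls. The other members went both ways, so the list median leans on this family. AS1, a regulator of leaf polarity and of class I KNOX genes, was at -0.58 ± 0.02. Of the 5 higher members, OSR1 was at 0.79 ± 0.09, ANT, which prolongs cell division in organ primordia, at 0.53 ± 0.02, ARL at 0.31 ± 0.03, ARGOS at 0.16 ± 0.07 and DA1 at 0.11 ± 0.04. Except for ANT, these were looked up after the count was known. Core cell cycle genes did not share the direction: 6 of 15 were called higher and 4 lower, or 5 and 6 with the median ratio set to 0, and their median went from 0.018 to -0.036. MCM2 of the replicative helicase was at 0.43 ± 0.02 and CYCD3;1 at 0.39 ± 0.02, while the cell cycle inhibitor KRP2 was at -0.29 ± 0.04.

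Boundary and meristem genes were also mostly lower, with CUC3 as the main exception. Of the 16 boundary genes, among them the targets of miR164, 9 were called lower and 3 higher, or 9 and 1 with the median ratio set to 0. The targets themselves were split, as looked up after the count was known. CUC1 at -0.19 ± 0.11 and ORE1 at -0.25 ± 0.07 were called lower. NAC080 at 0.13 ± 0.05 and NAC100 at 0.08 ± 0.04 were called higher. CUC2 at -0.05 ± 0.07 and NAC1 at 0.12 ± 0.10 were not called. CUC3, which miR164 does not target, had 1477 reads in DEX and 657 in mock, a log2 ratio of 1.39 ± 0.07. LSH3 was at -1.24 ± 0.10, KNAT6 at -0.64 ± 0.06 and BOP2 at -0.60 ± 0.05. The list median of -0.14 lay at percentile 0.11 of random lists. All 5 measured meristem genes were called lower, at a median of -0.44 and percentile 0.03. Among them KNAT1 was at -0.61 ± 0.04, KNAT2 at -0.54 ± 0.07, STM at -0.44 ± 0.03 and WUS at -0.24 ± 0.04. CLV1, looked up after the count was known, was only 1.04-fold lower, at a posterior of 0.969. The meristem genes thus did not share the size of their median. Genes of floral organ and meristem identity were split, with 8 of 20 higher, 8 lower and a median of -0.02, or -0.09 after correction for GC content and length, within the random range. Their leading members were AGL24 at -0.96 ± 0.09, SEP3 at -0.43 ± 0.02, AP3 at -0.23 ± 0.02 and AP2 at 0.40 ± 0.03.

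Auxin genes were lower more often than higher in DEX. Of 31 measured, 15 were called lower, 2 higher and 14 not called, with a median of -0.19 at percentile 0. Families within the list differed, as looked up after the count was known. All 5 GH3 genes were called lower. Of 11 IAA genes, 4 were called lower and 7 not called, with a median of -0.08. GH3.3, GH3.5 and GH3.6, which encode enzymes that conjugate auxin to amino acids, were at -0.58 ± 0.02, -0.39 ± 0.02 and -0.33 ± 0.02, and the efflux carrier gene PIN3 was at -0.50 ± 0.03. Cytokinin genes had 7 of 15 lower and 4 higher, with a median of -0.19 at percentile 0.05, or -0.09 without genes that have a near-identical copy, an alternative added after seeing the data. The cytokinin oxidase genes CKX3 and CKX5 were at -1.40 ± 0.06 and -0.54 ± 0.05, while CKX4, looked up after its value was seen, was at 1.19 ± 0.17, and the response regulators ARR7 and ARR4 at -0.69 ± 0.06 and 0.40 ± 0.03. Gibberellin genes had 9 of 17 lower and 4 higher, with a median of -0.15 at percentile 0.17. GASA6 was at -0.78 ± 0.03 and RGL2, a DELLA repressor, at -0.18 ± 0.02, against 0.41 ± 0.03 for GA2OX2 and 0.29 ± 0.01 for GASA4.

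Jasmonate genes went both ways, with 10 of 23 higher and 10 lower, or 6 and 13 with the median ratio set to 0. At 1.5-fold or more, however, 5 were lower and 0 higher. Among these, DAD1 was 3.38-fold and JAZ7 2.09-fold lower, both looked up after the count was known. MYC2, the main transcription factor of the pathway, was at -0.78 ± 0.02. The lipoxygenase gene LOX3 was at -0.62 ± 0.03 and the repressor gene JAZ9 at -0.35 ± 0.01, while LOX2 was at 0.29 ± 0.01. Brassinosteroid genes had 5 of 10 lower and 3 higher, or 5 and 2 with the median ratio set to 0. The biosynthesis genes CPD and BR6OX2 were at -0.53 ± 0.02 and -0.29 ± 0.04, and ROT3 at 0.44 ± 0.04. The medians of both lists, -0.01 and -0.05, lay within the central 95% of random lists. After correction for GC content and length, added after seeing the data, they were -0.13 and -0.10, and the jasmonate list then lay outside that range.

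The fixed list of wound, touch and defence genes was mostly higher in DEX. Of its 16 measured members, 12 were called higher and 2 lower, and the median of 0.35 lay at percentile 100 of random lists. WRKY40 and WRKY33, transcription factors induced by elicitors, were 2.30-fold and 2.07-fold higher, with counting errors of 0.06 and 0.03 on the log2 scale. The dehydration gene RD29A was at 0.81 ± 0.01 and the touch-induced calmodulin-like gene TCH3 at 0.42 ± 0.02. The 2 lower members, FRK1 and PR2, were at -1.26 ± 0.23 and -0.43 ± 0.23 and were looked up after the count was known. Gene sets from the annotations in the authors' deposited table, compared after the data were seen, differed in their placement. Response to chitin had 76 of 118 genes higher and 19 lower, at percentile 100 of random sets. Response to wounding had 64 of 133 genes higher and 49 lower, at percentile 72.8. Defence response had 95 of 269 higher and 60 lower, at percentile 35.9, and defence response to bacterium 61 of 168 higher and 64 lower, at percentile 6.75. Of 10 heat shock genes, 5 were called higher and 2 lower, with a median of 0.07 within the random range, which was 0.017 with the median ratio set to 0 and -0.014 without genes that have a near-identical copy. HSP23.6, which has a near-identical copy, was at 0.65 ± 0.09, HSP70 at 0.55 ± 0.03, HSP90.1 at 0.53 ± 0.04 and HSFA2 at 0.51 ± 0.10. Clock genes had 6 of 12 higher and 1 lower, or 5 and 3 with the median ratio set to 0, and their median of 0.10, or 0.02 after the GC and length correction, was within the random range. PRR5 was at 0.33 ± 0.02, FKF1 at 0.28 ± 0.02, TOC1 at 0.25 ± 0.01 and GI at 0.22 ± 0.01.

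Markers of other tissues in the buds also differed between the pools. Late pollen genes were higher for 4 of 5 members, with a median of 0.35 at percentile 99.8. VGD1 was at 0.37 ± 0.01, AGP11 at 0.35 ± 0.02, AGP6 at 0.29 ± 0.01 and PPME1 at -0.28 ± 0.03, and PPME1 has a near-identical copy. Tapetum and exine genes had 13 of 17 higher and 2 lower, or 7 and 4 with the median ratio set to 0. Their median of 0.07 was within the random range, was 0.017 with the median ratio set to 0, and lay outside the range at 0.05 after the GC and length correction. MS1 was at 0.57 ± 0.05 and ACOS5 at 0.16 ± 0.01. Carpel and ovule genes had 4 of 9 lower and 0 higher, or 6 and 0 with the median ratio set to 0, and their median of -0.07, or -0.13 after the GC and length correction, was within the random range. CRC was at -0.26 ± 0.04 and HEC2 at -0.41 ± 0.17. Photosynthesis genes had 11 of 13 lower and 2 higher, or 11 and 1 with the median ratio set to 0, with a median of -0.14 at percentile 0.75. LHCB2.1 was at -0.52 ± 0.02, LHCB4.1 at -0.28 ± 0.01 and RBCS1A at -0.13 ± 0.0031. RBCS3B, at -0.45 ± 0.01, shares near-identical sequence with RBCS2B, which was 1.34-fold higher, so the reads of both are uncertain.

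**Figure D3:**
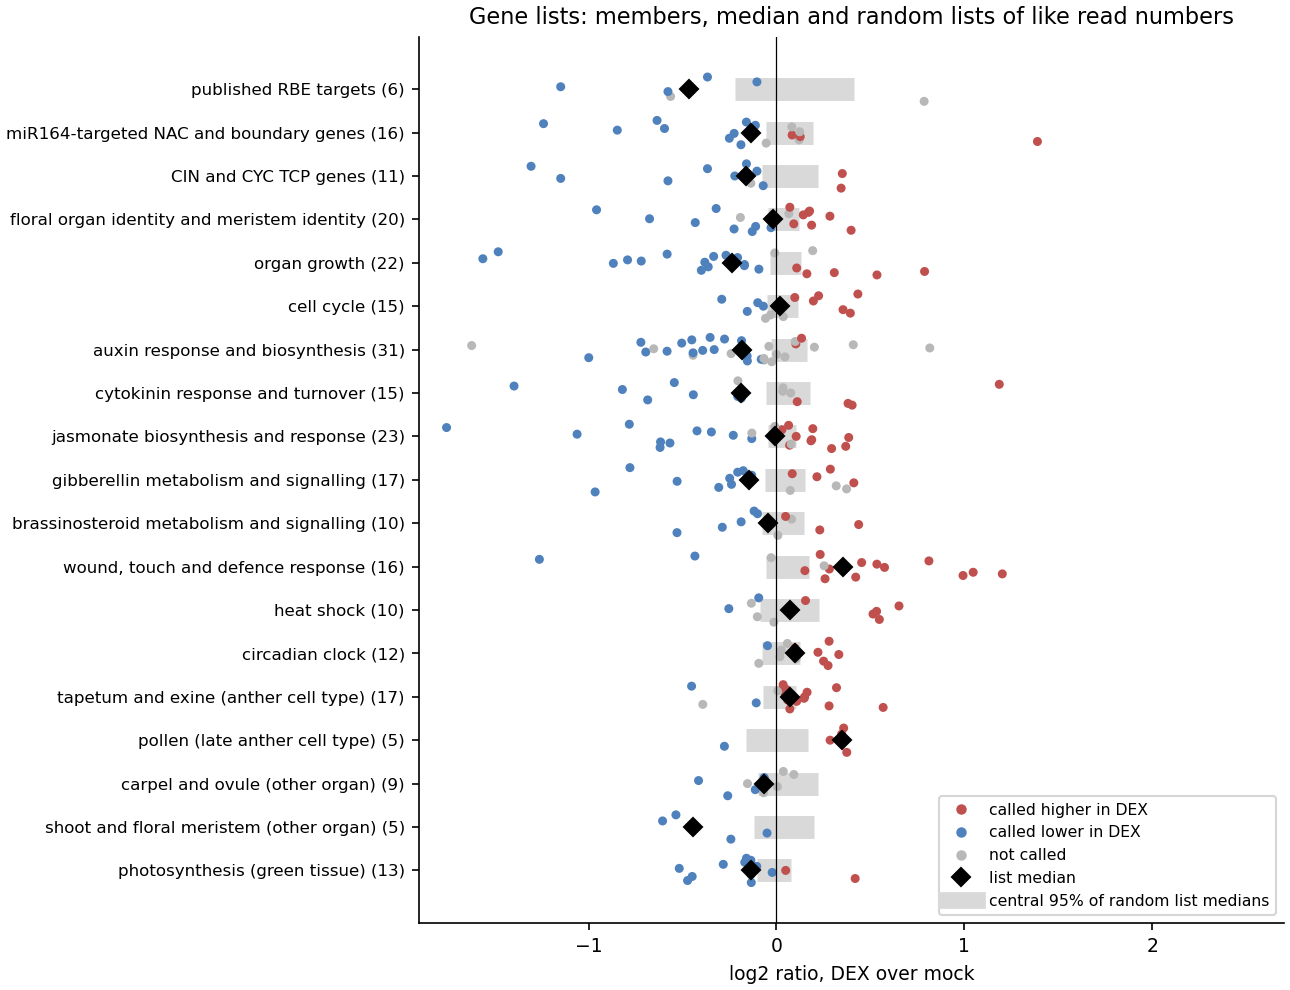
Log2 ratio of DEX over mock for the members of 19 gene lists (points, coloured by call, number measured in parentheses), with the list median (black diamond). Grey bars span the central 95% of medians of 10000 random lists matched on reads. The medians of 2 lists lie above their bar and those of 9 below it.

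The list placements compare pooled libraries, and 11 of 19 lists outside the central 95% is a description without a replicate test. Of the 74 list members that the rule names, 16 overlap a gene on the other strand, among them GRF7, GRF3, AS1, MYC2, WRKY33 and WRKY40, and WRKY40 also has a near-identical copy. Their reads are uncertain where the counting did not use strand.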

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

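No paired analysis was possible because the deposited values are pooled over replicates. For the same reason the planned count models with other size factors or tests and the planned set tests across samples were not run. Separate technical replicates, a replicate block and the removal of a replicate were also not run, and scaling by total reads was already the main setting. The numbers of called genes moved by more than 1.5 times only with a fold limit: from 9081 to 1109 higher and from 5183 to 727 lower at 1.5-fold, and to 434 and 243 at 2-fold, the latter added after seeing the data. Both limits leave fewer genes by construction. A posterior limit of 0.01 gave 7254 higher and 4255 lower. Apart from the fold limits, the fewest higher genes came with the median of ratios, 6339 higher against 7352 lower, which moved the share of higher genes among calls from 63.7% to 46.3%. Genes with reads in 1 pool would add 434 and 474 calls, of which 253 and 312 rest on 1 read. The 20 genes with the largest ratios kept their direction and call in all 60 values. The settings were a posterior limit of 0.01, the median of ratios and the removal of the 1% most abundant genes from the totals. The last was added after seeing the data. This outcome was fixed in advance. All 20 genes had a posterior of 1, and the 2 scalings shift every ratio alike, by only 0.05 and 0.013. RBE ranged from -0.24 to -0.19. Of the 207 called list genes, 186 stayed called at a posterior limit of 0.01 and 36 had a ratio of 1.5-fold or more. The number of lists outside the central 95% of random lists was 11 in the main setting, 11 with a mean of at least 20 counts per biological sample, 11 without genes that have a near-identical copy and 13 after correction for GC content and length, the latter pair added after seeing the data. The correction brought in the jasmonate list at -0.13 and the tapetum list at 0.05, and the cause was not tested. Of 76 list medians under alternatives, 0 that lay outside came back within and 0 of these changed sign. The median of ratios shifts the random lists by the same amount, so it could not change a placement. The cytokinin median moved from -0.19 to -0.09 without genes that have a copy. Among lists within the random range, 5 medians changed sign: cell cycle from 0.018 to -0.036 with the median of ratios, -0.015 after the GC and length correction and -0.0060 without copies, heat shock from 0.07 to -0.014 without copies, and jasmonate from -0.0089 to 0.010 with the filter on 20 counts. The cause of these moves was not tested. Depth limits the MIR164 genes, with at most 41 reads, while most genes are limited by the missing spread between replicates.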

Other observations

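The gene annotations carried in the authors' deposited table gave 457 terms with 15 to 300 genes of at least 80 reads, chosen for comparison after the data were seen. Of these, 37 lay in the top 0.5% of random gene sets matched on reads and 51 in the bottom 0.5%. For independent genes and terms, 2.29 per side would be expected. Terms share members, and genes of a term can vary together between pools, so the excess over that number is a description and no test. Cell wall loosening was lower in DEX, with 14 of 23 genes called lower, 3 higher and a median of -0.31. The expansin genes EXPA5, EXPA10 and EXPA8 were at -1.53 ± 0.04, -1.03 ± 0.04 and -0.99 ± 0.03. Wax biosynthesis had 9 of 15 genes lower and 5 higher, with a median of -0.30. Its lowest members were CYP96A15, a mid-chain alkane hydroxylase, at -1.18 ± 0.02, CER2 at -0.77 ± 0.03 and KCS6, a fatty acid elongase, at -0.73 ± 0.01. Flavonoid biosynthesis had 13 of 19 genes lower and 1 higher, with the regulator gene MYB12 at -0.88 ± 0.10.

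Among terms higher in DEX, DNA replication had 40 of 48 genes called higher and 3 lower, with a median of 0.23. The ribonucleotide reductase gene RNR1 was at 0.53 ± 0.02, POLA3 at 0.52 ± 0.04 and ORC6 at 0.49 ± 0.06. By these annotations, 0 of the 48 genes are in the cell cycle list. Response to chitin had 76 of 118 genes higher and 19 lower, with a median of 0.18, and it shares 5 genes with the wound, touch and defence list. The larger terms on wounding and defence given with that list lay within the central 95% of random sets. EDA39 was at 1.44 ± 0.04 and the ubiquitin ligase gene PUB24 at 1.21 ± 0.11. Response to hypoxia had 12 of 18 genes higher and 2 lower, with the alcohol dehydrogenase gene ADH1 at 13586 reads in DEX and 7380 in mock. Monovalent cation and proton exchangers had 17 of 22 genes higher and 1 lower, with a median of 0.44. Pollen sperm cell differentiation had 18 of 26 genes higher and 4 lower, with the DUO1-activated genes DAF1 and DAZ3 at 0.73 ± 0.01 and 0.72 ± 0.05. Chloroplast-encoded genes with at least 200 reads had 23 of 43 called higher and 2 lower in these poly-A libraries, and mitochondrial genes 6 of 16 higher and 0 lower.

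The tests below were chosen after the results were seen, except that of near-identical copies. Growth-regulator genes were lower in DEX, with a median of -0.24 in the organ growth list, a value that leans on its 9 GRF genes. A smaller share of young dividing tissue in the DEX buds would lower cell cycle genes alike. Only 1 of the 15 cell cycle genes, the inhibitor KRP2, lay at or below -0.24. In these pools that goes against an equal loss across both lists. The DNA replication term, picked after the data were seen, had 40 of 48 genes higher and 3 lower, at a median of 0.23. For those genes, these values argue against a loss of dividing tissue. The cell cycle comparison does not exclude a smaller loss, because the value compared leans on 1 gene family. Dilution by more late anther tissue would put the cell cycle median at or below 0.5 times the organ growth median. The cell cycle median was 0.018 with a bootstrap standard error of 0.07. With the median ratio set to 0 it was -0.036, against -0.29 for organ growth. With an error of this size, dilution is not excluded. A smaller share of meristem was not excluded. Its 5 genes were lower at a median of -0.44, but unequally, with WUS 1.18-fold and CLV1 only 1.04-fold lower. With no dexamethasone-treated plants without the transgene among the groups, effects of RBE and of dexamethasone on these genes remain untested alternatives, and variation between replicates was not measured.

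More genes were called higher than lower in DEX, 63.7% of all calls. Abundant genes that are lower in DEX might pull the scaling by total reads, but leaving out the 249 most abundant genes moved every log2 ratio by -0.013, against a median of 0.04 among genes with at least 200 reads. The share of higher calls was then 59.7%. With the median ratio set to 0 it was 46.3%, so the excess of higher calls depends on the centring chosen. Genes with 10 to 50 reads lay 0.19 above genes with 3000 or more in median log2 ratio. After removal of trends with GC content and length the excess was 0.18 with a bootstrap standard error of 0.01, so these trends do not account for it. Background reads that differ between libraries stay open, as does a biological difference.

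The 20 genes with the largest ratios in either direction might owe them to reads shared between near-identical gene copies. Of these, 2 had such a copy at 95% identity or more, DTX1 and FRO6, against a range of 0 to 3 in the central 95% of random sets matched on reads. At 80% identity, a limit added after seeing the data, 8 had a copy against a range of 2 to 10. These counts lay at percentiles 92.5 and 86.9 of the random sets. The 8 were SBT3.3, AT1G17147, DTX1, AT3G61111, ATCSLA15, ERD2, OASA2 and FRO6. Of all 427 genes with 200 reads or more and a copy at 95% identity, 4.7% differed by at least 1.5-fold, against 4.9% without one. Most of the 20 genes have no copy at 95% identity, so such copies do not account for the whole set. A count among 20 genes cannot exclude a part for looser copies, and the reads of DTX1 and FRO6 stay uncertain. Whether these genes differ by as much in each biological replicate remains open.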
